A study of Rattus norvegicus with 4 samples.

How the data were processed

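MicroRNAs (miRNAs) of the fracture callus, the repair tissue that bridges a broken bone, were measured in control rats and in rats made diabetic with streptozotocin, a toxin of the insulin-producing beta cells. The callus was taken 5 or 11 days after the fracture. Per the labels, the tissue of 5 animals was pooled for each group and day, so that each of the 4 arrays stands for 1 pool and no group has a replicate. Per the labels' protocols, the pooled tissue was submitted to the array's maker for RNA isolation and microarray analysis, and total RNA was extracted with a column kit and labelled with the Cy5 dye of the 3D-Gene miRNA labelling kit. Each array held 727 rat miRNA probes with 1 spot each, 1504 blank spots and 8 spots each of 2 spike controls.

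The deposited scanner files gave, per the file headers, the median intensity of each spot and the median intensity of its local background, with no background subtracted. The scanner software had marked 1 spot as not usable, a spike control, and 0 miRNA spots. The authors' deposited value table held 1 linear intensity per miRNA and array, with null given for some miRNAs. How it was made was not given in the sources used here, and its scale was found by setting it against the scanner files. Each deposited value was the spot intensity minus the mean of the array's blank spots (with the highest and lowest 5% left out), multiplied by 1 factor per array that set the median of the listed values to 25, with largest deviations of 0.114, 0.0894, 0.101 and 0.105% on the 4 arrays. A miRNA was listed where its spot was above the blank mean plus 2 SD, with 1 more listed than this limit gives on the control day 11 array. Because the number of listed miRNAs differed (504, 560, 502 and 482 for control day 5, diabetic day 5, control day 11 and diabetic day 11), that scaling shifted whole arrays. The median log2 difference over miRNAs listed on both arrays was 0.34 for diabetic minus control on day 5, -0.026 for the same on day 11, 0.10 for day 11 minus day 5 in control and -0.29 for day 11 minus day 5 in diabetic callus. The deposited values were therefore used only as an alternative.

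The design, the alternatives, the lists and the rule for named miRNAs were fixed before the data were examined. The main values were the scanner intensities corrected for local background with limma's normexp method (offset 50) over all spots and quantile-normalised over the 727 miRNA spots, on the log2 scale. A miRNA counted as detected on an array where its spot exceeded the blank mean plus 2 SD, and it entered a comparison if it was detected on at least 1 of the 2 arrays. The local background turned out to follow the spot. The correlation of log2 background with log2 spot intensity across miRNA probes was 0.808, 0.758, 0.953 and 0.889 on the control day 5, diabetic day 5, control day 11 and diabetic day 11 arrays. Of the spots at least 10 blank SDs above the blank mean, 39 of 285, 27 of 273, 132 of 260 and 109 of 263 had a background of at least 50% of the spot on these arrays in that order, and on the control day 11 array 2 had a background at or above the spot. For this reason a second value is given beside the main value. The blank-corrected intensity was the spot minus the blank mean, scaled so that the median of the 400 miRNAs detected on all 4 arrays was 100 on each array, which is the scale of the alternative with blank-spot subtraction and median scaling. The use of these values beside the main ones, and the counts of miRNAs that are 2-fold different under both corrections, which cover only miRNAs detected on both arrays, were chosen after the data had been seen. The authors' values had first been set beside the main values, and were replaced because of the shifts given above. Normexp on the blank-spot mean was also added after the data had been seen. In the text, main value means normexp on the local background, and levels and folds are blank-corrected unless said otherwise. The main values compress differences of dim miRNAs because of the offset.

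The precision is limited by the number of arrays, which is 1 per group. A technical error was attached to blank-corrected differences. It combined the log2 SD of the spike spots on each array, between 0.06 and 0.20, with the SD of the blank spots, which was 5.01, 5.61, 5.73 and 5.93 on the blank-corrected scale. It leaves out the spread between animals, pools and hybridisations. The diabetic day 11 array was dimmer than the rest, with a mean spike control 1 intensity of 14528 against 34093, 31916 and 36103 and a blank mean of 73.4 against 120.0, 117 and 141.

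The comparisons were diabetic minus control on each day and day 11 minus day 5 in each group. For these, log2 differences of at least 1 (2-fold) were counted and no p-value was computed. Where 1 of the 2 arrays did not detect a miRNA, the fold is a bound against the higher of that array's lowest detected value and the miRNA's own value there. Pairs of differences that share no array were set against each other by their correlation across miRNAs, which are not independent replicates, and by the number 2-fold in the same direction beside the number expected of independent lists. The only test, on the main values, was limma's moderated linear model (lmFit and eBayes) with diabetes and day as additive terms over the 4 arrays. It had 1 residual degree of freedom and Benjamini-Hochberg adjustment over 639 miRNAs detected on at least 1 array. There the days stand in for replicates.

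miRNA lists were written from general knowledge: cartilage miRNAs, osteoblast differentiation miRNAs, the miR-29, miR-30 and let-7 families, proliferation clusters (the miR-17, miR-106b and miR-106a clusters), the miR-15/16 seed family, mesenchymal and smooth muscle miRNAs, the imprinted Dlk1-Dio3 cluster, the miR-221/222 and miR-181 families, a hypoxia list (miR-210), the miR-23/27/24 clusters and the p53-linked miR-34 family. Markers of other cells and tissues were skeletal muscle, leukocyte, erythroid, endothelial, epithelial, neural, and liver and pancreas miRNAs. For lists with at least 4 detected members, the median difference was placed among 10000 random lists of the same size matched on mean expression in 10 bins. A list member detected on 1 of the 2 arrays entered with its main value and, blank-corrected, with the floor of the lowest detected value on the other array, so that dim members detected on 1 array differ by construction. This percentile describes these arrays and is no test. Random lists draw unrelated miRNAs, whereas members of a list can be arms or neighbours of 1 transcript that move together. Extreme percentiles are then easier to reach. Names are those of the array, and a list name with no exact match was matched without its arm or without the letter a after its number.

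Named were, in each comparison, the 8 miRNAs with the largest positive and the 8 with the largest negative main difference among those detected on both arrays with a mean at or above the median, up to 4 with the largest bound among those detected on 1 array, the 10 with the highest mean over the 4 arrays, the detected members of a list that is discussed, and up to 5 per direction with the smallest adjusted p in the additive fit. miRNAs named outside this rule are said to have been chosen after their values were seen.

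The scripts were tested on simulated data with 200 miRNAs changed in the diabetic arrays and no link between background and spot. On day 5 the main setting recovered 54.6% of changes of log2 1.5 and 74.5% of changes of log2 2 as 2-fold (671 miRNAs), and on day 11 55.1% and 70.6% (680 miRNAs), with 0% of unchanged miRNAs called. Blank-spot subtraction recovered 94.8% and 100% on day 5 and 95.9% and 100% on day 11, and called 3.18% and 3.54% of unchanged miRNAs. The additive fit (688 miRNAs) recovered 90.8% and 96.1% of the simulated diabetic changes and called 4.71% of unchanged miRNAs. The simulated changes were the same on both days, with little noise and no spread between pools. These shares therefore do not give the power of the fit in the real data. Alternatives covered the scaling between arrays, the background correction, the filter on dim probes, the authors' values, the fold that counts, the block and prior of the fit, and the matching of random lists. No genome coordinates were used, because the files name no genome build. R 4.3.3 with limma 3.58.1 was used for the analysis, and Python 3.11.15 with matplotlib 3.10.9 for plots.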

Results

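The miRNA content of the fracture callus was profiled on 4 one-colour arrays, 1 each for control and diabetic rats on days 5 and 11 after a closed fracture of the femoral shaft. The rats were 12-week-old Sprague-Dawley males. Diabetes was induced with 1 intravenous dose of 40 mg/kg streptozotocin, and the diabetic animals had a blood glucose above 300 mg/dl, per the labels. Each array carried RNA from the pooled tissue of 5 animals, so no difference between 2 arrays has a replicate check. The comparisons ask which miRNAs differ between diabetic and control callus on each day and between the days within each group. Levels are blank-corrected intensities. Where 2 log2 differences, list medians or percentiles stand together, the blank-corrected one comes first and the main one, with the local background, second.

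Of 727 rat miRNAs, 504 (69.3%) were detected in control callus on day 5, 560 (77.0%) in diabetic callus on day 5, 501 (68.9%) in control callus on day 11 and 482 (66.3%) in diabetic callus on day 11. On all 4 arrays 400 miRNAs were detected and on none of them 88. The 10 brightest miRNAs by mean main value were miR-375-5p, miR-21-5p, miR-199a-3p, miR-347, miR-16-5p, miR-23a-3p, miR-23b-3p, let-7c-5p, let-7a-5p and miR-199a-5p. The level of miR-21-5p, an abundant miRNA of stroma and inflamed tissue, was 33896 in control and 25787 in diabetic callus on day 5, and 18534 and 24454 on day 11. That of miR-199a-3p, a miRNA of mesenchymal cells, was 12629 and 12998 on day 5 and 15798 and 19065 on day 11.

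The diabetic callus was first compared with the control callus on day 5, an early stage of the repair. Most leukocyte miRNAs and both detected endothelial miRNAs were lower in the diabetic callus, and miR-451-5p and most detected miRNAs of the miR-181 family were higher. miR-223-3p, which is abundant in neutrophils and monocytes, was 1.81-fold lower in the diabetic callus, at 3130.4 against 5675 (log2 -0.86 ± 0.17 technical error, main -1.04). The paired arms miR-142-3p and miR-142-5p, which are expressed across blood cell lineages, were 1.49-fold and 1.44-fold lower, with main log2 differences of -0.68 and -0.69. Of 10 detected leukocyte miRNAs 6 were lower and 2 higher under both corrections. Their median was -0.48 and -0.38, at percentiles 0 and 0.01 of random lists. miR-155-5p, a miRNA of activated lymphocytes and macrophages, was among the higher ones, at 102 against 71.5.

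miR-451-5p, a miRNA of red blood cells and their precursors, was 2.79-fold higher in the diabetic callus on day 5, at 1357 against 486 (log2 1.48 ± 0.18 technical error, main 1.19). Among miRNAs detected on both arrays it was the only one that was 2-fold different under both corrections. miR-144-3p, transcribed together with miR-451, was at 88.3 against 26.5, with log2 differences of 1.74 and 0.51. Of 3 detected erythroid miRNAs 2 were higher under both corrections. The 7 detected members of the miR-181 family, which is studied for its part in lymphocyte development, had a median difference of 0.80 and 0.41, at percentiles 99.9 and 99.98. Of these, 6 were higher under both corrections, among them miR-181a-5p at 1128 against 826 and miR-181b-5p at 213 against 122. On day 11 the family had a median difference of -0.034 and 0.14 (percentiles 34.2 and 75.3).

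The only epithelial miRNA detected on both arrays of day 5, miR-205, was at 62.1 against 49.3 (log2 0.33 and 0.32), and 4 others were detected in diabetic callus alone, at levels of 19.4 to 42.6. Without the detection filter the main median of the 8 epithelial miRNAs was 0.0052. The 2 endothelial miRNAs were miR-126a-3p (log2 -0.35 and -0.39) and miR-126a-5p (-0.29 and -0.50), with a median of -0.32 and -0.44. The 6 cartilage miRNAs had a median of 0.11 and 0.13 (percentiles 77.4 and 87.3), and miR-140-5p was at 829 against 785. The 11 detected skeletal muscle miRNAs had a median of 0.10 and 0, with miR-1-3p at 8787 against 8527. The miR-23/27/24 clusters had a median of 0.21 and 0.17 (percentiles 99.5 and 93.5). Their brightest members miR-23b-3p and miR-23a-3p had main differences of 0.79 and 0.72 and blank-corrected differences of 0.028 and -0.030. miR-140-3p (0.15 and 0.70), miR-92b-5p (0.29 and 0.85) and miR-30b-5p (-0.32 and 0.62) differed between the corrections in the same way. The miR-15/16 seed family had a median of -0.11 and -0.26 (percentiles 25.1 and 2.92), with miR-497-5p 1.43-fold lower.

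Among the remaining miRNAs with the largest main differences on day 5, miR-532-5p was 2.62-fold higher (259.6 against 99.2) and miR-133a-5p 1.81-fold higher. miR-151-3p was 2.56-fold lower (70.1 against 179) and miR-6216 2.09-fold lower (570.2 against 1191), each with a main difference short of 2-fold. miR-100-5p and miR-3473 were 1.32-fold and 1.22-fold lower. Of these 2 arrays only control callus showed miR-344a-3p, at 111, and it was at least 2.53-fold lower in diabetic callus by the main values and at least 9.88-fold blank-corrected. Bounds, blank-corrected and main, were at least 1.82-fold and 1.48-fold lower for miR-3585-5p, 1.76-fold and 1.46-fold higher for miR-190a-3p and 3.21-fold and 1.46-fold higher for miR-202-3p. In all, 1 miRNA was 2-fold higher and 2 were 2-fold lower among 596 in the main values. Blank-corrected, 20 were higher and 12 lower among the 468 detected on both arrays.

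The comparison on day 11 covers a later stage, when the callus of a closed fracture typically holds cartilage. Cartilage miRNAs were lower in the diabetic callus, and most miRNAs of the proliferation clusters and of the imprinted Dlk1-Dio3 cluster were higher. miR-140-5p and miR-140-3p, the arms of the miRNA hosted by the gene Wwp2 and abundant in chondrocytes, were 3.16-fold and 3.32-fold lower in the diabetic callus. Their levels were 2111 against 6675 (log2 -1.66 ± 0.11 technical error, main -1.76) and 3187 against 10566 (log2 -1.73 ± 0.11, main -1.48). miR-455-5p and miR-455-3p, hosted by the collagen gene Col27a1, were 2.98-fold and 2.56-fold lower, with main differences of -1.55 and -2.26. miR-675-3p, made from the H19 transcript, was at 34.2 against 82.8, and its other arm miR-675-5p was at 149 against 174. All 6 cartilage miRNAs were thus lower under both corrections, with a median of -1.46 and -1.51 that lay below every random list (percentile 0 in both). On the same arrays the blank-corrected medians were 0.17 for skeletal muscle, 0.049 for leukocyte and 0.061 for endothelial miRNAs, and erythroid miR-451-5p was at 1458 against 1495. The main medians were 0.15 for skeletal muscle, -0.18 for leukocyte and 0.43 for endothelial miRNAs. That of the 2 detected erythroid miRNAs was 1.98, with a blank-corrected median of -0.0046. The 6 detected epithelial miRNAs had a median of 0.58 and 0.17 (percentiles 98.2 and 88.3), with 3 higher and 0 lower under both corrections. Of these, only miR-205 (58.8 against 35.8) and miR-203a-3p (19.1 against 45.4) were detected on both arrays.

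**Figure D1:**
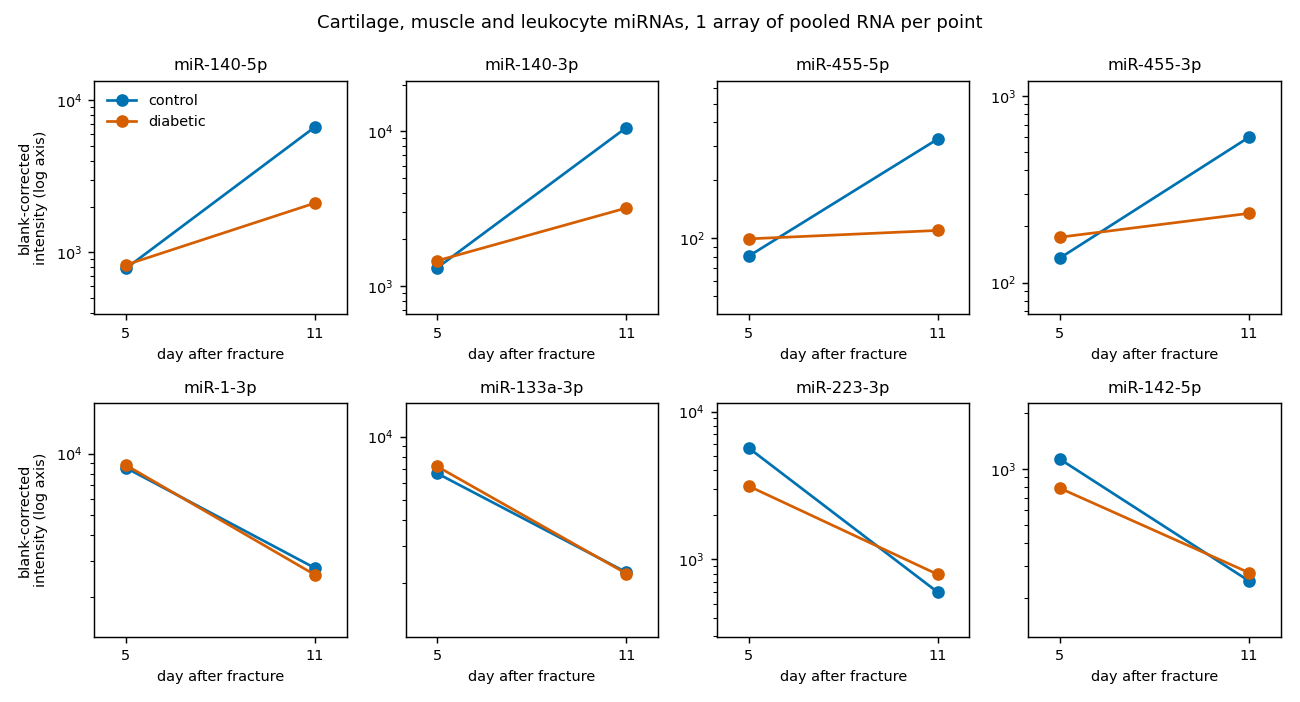
Blank-corrected intensity of 4 cartilage miRNAs (top) and 4 muscle and leukocyte miRNAs (bottom) against the day after fracture. Intensities are on a log axis and scaled so that the median of 400 common miRNAs is 100. Each point is 1 array of RNA from the pooled tissue of 5 rats, without error bars. Lines join the days of control (blue) and diabetic (orange) callus. miR-140-5p stood at 785 on day 5 and 6675 on day 11 in control callus, and at 829 and 2111 in diabetic callus.

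The proliferation clusters, 3 related clusters that are active in dividing cells, were higher in the diabetic callus on day 11. Of their 10 detected members 9 were higher under both corrections, and the median was 0.48 and 0.44 (percentiles 99.79 and 99.02). miR-19a-3p was at 127 against 72.9, miR-18a-5p at 88.8 against 59.1 and miR-17-5p at 1005 against 667. The exception, miR-20b-5p, had differences of 0.41 and -0.78. Of 44 detected members of the Dlk1-Dio3 cluster, an imprinted miRNA cluster of embryonic and mesenchymal tissue, 29 were higher and 6 lower under both corrections. Their median was 0.64 and 0.18 (percentiles 100 and 99.77). miR-379-5p was at 309.6 against 147 (log2 1.08 and 1.19), miR-411-3p at 135 against 65.3 and miR-127-3p at 231 against 127.

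miR-210-3p, a miRNA induced by hypoxia, was at 263 against 546 on day 11 (log2 -1.05 and -0.98). On day 5 it was at 92.8 against 145 (log2 -0.64 and -0.47). Its other arm miR-210-5p had differences of -0.36 and 0.16 on day 11 and 0.38 and 0.36 on day 5. miR-221-3p was at 778 against 367 on day 11 (log2 1.08 and 0.76) and miR-222-3p at 119 against 81.6 (log2 0.54 and 0.25). miR-6216 was 2.09-fold lower (log2 -1.06 and -1.38). miR-100-5p and miR-99a-5p, which share a seed sequence, were 1.90-fold and 1.67-fold lower, with main differences of -1.52 and -2.17. let-7i-5p had a main difference of -1.36 and a blank-corrected one of -0.070.

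The 8 largest positive main differences on day 11 had no counterpart of like size in the blank-corrected values. miR-26a-5p (-0.081 and 6.04), miR-125b-5p (-0.34 and 5.56), miR-451-5p (-0.036 and 3.63) and miR-26b-5p (-0.051 and 2.35) were of opposite sign. miR-199a-5p (0.30 and 1.74), miR-211-3p (0.30 and 1.66), miR-3573-3p (0.18 and 1.46) and miR-3068-3p (0.066 and 1.26) were smaller. On the control day 11 array the local background of these 8 spots was between 75.4% and 106% of the spot. miR-3587 was detected in the diabetic callus and not in the control callus, at 117, and was at least 2.36-fold higher by the main values and at least 10.2-fold blank-corrected. Bounds, blank-corrected and main, were at least 1.60-fold and 1.80-fold lower for miR-30b-3p, 1.36-fold and 1.54-fold higher for miR-200b-3p and 1.17-fold and 1.498-fold lower for miR-3595. In all, 13 miRNAs were 2-fold higher and 16 lower among 550 in the main values. Of these 29, 20 involved a spot whose local background was over 50% of it. Such backgrounds were common on the control day 11 array, at 132 of 260 spots at least 10 blank SDs above the blank mean. That share covers bright spots of 1 array, whereas the 20 were counted by the higher background of the 2 arrays. Whether 20 of 29 is an excess was therefore not determined. Blank-corrected, 17 were higher and 21 lower among 433. Under both corrections 1 of these was higher, miR-379-5p, and 8 were lower, among them both arms of miR-140 and of miR-455.

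**Figure D2:**
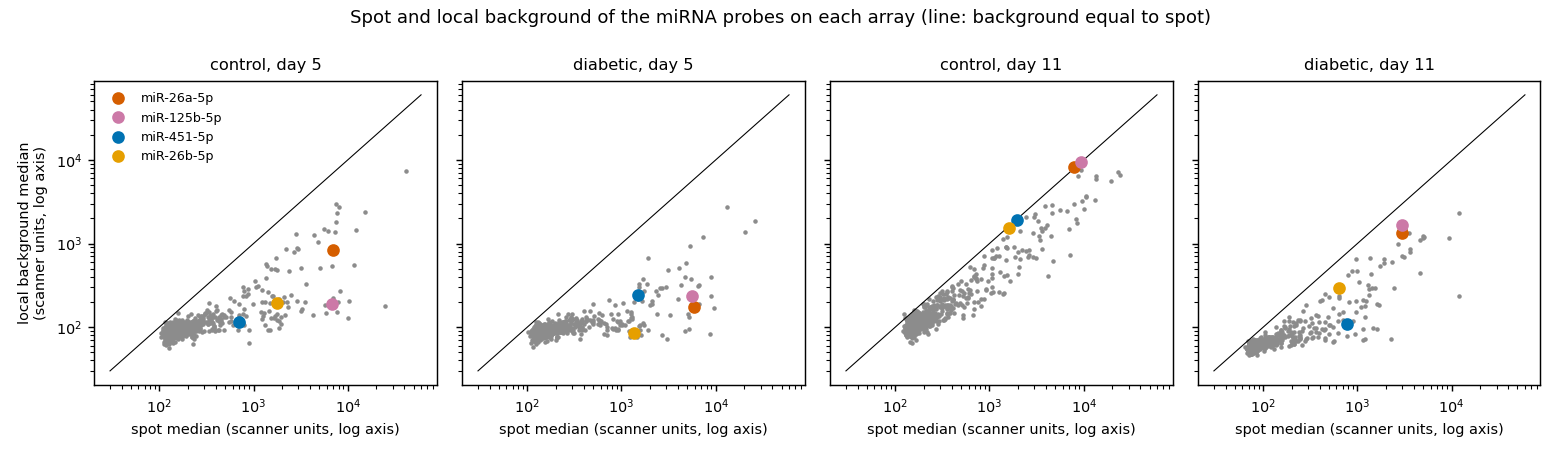
Median intensity of the local background against that of the spot for the 727 miRNA probes on each of the 4 arrays (scanner units, log axes), with the line of equal values and with 4 miRNAs marked. On the control day 11 array the correlation of the log values is 0.953, and the backgrounds of miR-26a-5p and miR-125b-5p are 106% and 100.3% of the spot.

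The course of healing in control callus was described by day 11 against day 5. Cartilage miRNAs were higher on day 11, and most muscle, leukocyte and proliferation-cluster miRNAs were lower. miR-140-5p and miR-140-3p were 8.50-fold and 8.07-fold higher (log2 3.09 ± 0.17 and 3.01 ± 0.17 technical error, main 3.17 and 3.31). miR-455-3p was 4.44-fold higher (601 against 135) and miR-455-5p 4.05-fold higher (327 against 80.7), while miR-675-5p and miR-675-3p were 1.36-fold and 1.12-fold higher. All 6 cartilage miRNAs were higher under both corrections, with a median of 2.08 and 2.08, above every random list (percentile 100 in both). This comparison shares the control day 11 array with the diabetic comparison of day 11. miR-210-3p was 3.76-fold higher, at 546 against 145 (main 1.56), and miR-210-5p was at 0.083 and -0.36.

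Most skeletal muscle miRNAs were lower on day 11 in control callus. miR-1-3p, a miRNA of skeletal and heart muscle, was at 2767 against 8527 (log2 -1.62 and -1.80), miR-133a-3p at 2246 against 6665, miR-133b-3p at 2680.4 against 8301 and miR-206-3p, a miRNA of skeletal muscle, at 1667 against 4611. miR-499-5p, hosted by a myosin gene, was at 50.9 against 253. Of 10 detected muscle miRNAs 8 were lower under both corrections and the median was -1.22 and -1.05 (percentile 0 in both). Among leukocyte miRNAs, miR-223-3p was 9.49-fold lower (598 against 5675, main -4.63, with a background of 80.2% of the spot on day 11). miR-142-5p was 4.55-fold lower (248 against 1129), and miR-150-5p, a lymphocyte miRNA, was at 119 against 411. The 10 detected leukocyte miRNAs had a median of -0.95 and -0.32 (percentiles 0.01 and 3.83), and 7 of them were lower under both corrections.

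The proliferation clusters were also lower on day 11 in control callus, with 10 of 11 detected members lower under both corrections and a median of -1.01 and -0.76 (percentiles 0.03 and 0.24). miR-19a-3p was at 72.9 against 268, miR-18a-5p at 59.1 against 192 and miR-17-5p at 667 against 1452. The Dlk1-Dio3 cluster had 27 members lower and 7 higher under both corrections among 45 detected, with a median of -0.56 and -0.15 (percentiles 0 and 0.67). This fall and the cluster's higher level in diabetic callus on day 11 rest on the same control day 11 array. Its medians without that array were 0.014 and -0.021 (diabetic minus control, day 5) and 0.038 and -0.020 (diabetic callus over time). For the proliferation clusters both comparisons share that array too. The miR-181 family was higher, with 6 of 7 members higher under both corrections and a median of 1.26 and 0.38 (percentiles 99.99 and 96.7). Its member miR-181a-5p was at 2327 against 826. This rise and the family's higher level in diabetic callus on day 5 share the control day 5 array. The family's medians without that array were -0.034 and 0.14 (diabetic minus control, day 11) and 0.43 and 0.36 (diabetic callus over time). The miR-23/27/24 clusters had a median of 0.72 and 0.69 (percentiles 98.6 and 94.6), with miR-23a-3p at 10848 against 6580.1. Endothelial miR-126a-3p was 1.76-fold lower, with a main difference of -1.73.

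Of the other miRNAs with large main differences in control callus, miR-878 was 2.00-fold higher, miR-351-5p also 2.00-fold and miR-128-2-5p 1.82-fold higher. miR-125b-5p (0.45 and -6.45), miR-26a-5p (0.16 and -6.44) and miR-451-5p (1.62 and -2.27) had opposite signs under the corrections, and miR-26b-5p was at -0.18 and -3.03, with the high local backgrounds of the control day 11 array given above. miR-344a-3p was detected on day 5 and not on day 11, and was at least 9.67-fold lower blank-corrected and at least 2.40-fold by the main values. miR-129-5p (at least 2.03-fold higher blank-corrected and 1.73-fold by the main values), miR-3595 (1.36-fold and 1.73-fold) and miR-96-3p (3.17-fold and 1.68-fold) were detected on day 11 and not on day 5. In all, 19 miRNAs were 2-fold higher and 27 lower among 559 in the main values. Of these, 22 involved a local background over 50% of the spot, and whether this is an excess was again not determined. Blank-corrected, 31 were higher and 31 lower among 446. Under both corrections 10 of these were higher and 10 lower.

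In diabetic callus, most muscle and leukocyte miRNAs were again lower on day 11 than on day 5, and both arms of miR-140 were higher. miR-1-3p was 3.43-fold lower (2564 against 8787), miR-133a-3p 3.25-fold, miR-133b-3p 3.06-fold and miR-133a-5p 2.96-fold lower. Of 11 detected muscle miRNAs 10 were lower under both corrections, with a median of -1.08 and -0.54 (percentiles 0 and 0.02). miR-223-3p was 3.97-fold lower (789 against 3130.4), miR-150-5p 3.18-fold and miR-142-5p 2.86-fold lower. Of 10 leukocyte miRNAs 9 were lower under both corrections, with a median of -0.75 and -0.51 (percentiles 0.04 and 0.105). The proliferation clusters had a median of -0.50 and -0.44 (percentiles 0.97 and 0.83), with 10 of 11 members lower under both corrections.

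miR-140-5p was 2.55-fold higher on day 11 in diabetic callus (2111 against 829, log2 1.35 ± 0.12 technical error, main 1.11) and miR-140-3p 2.19-fold higher (log2 1.13 ± 0.12, main 1.13). miR-455-5p was at 109.8 against 99.3 and miR-455-3p at 235 against 175, while miR-675-5p was at 149 against 126 and miR-675-3p was 2.13-fold lower (log2 -1.09 and -0.36). The cartilage list had a median of 0.33 and 0.27 (percentiles 83.3 and 91.1). Whether the difference between the days depended on the group was not tested, since each group has 1 pool per day. miR-210-3p was 2.83-fold higher (263 against 92.8), and miR-210-5p was lower (log2 -0.65 and -0.56). The Dlk1-Dio3 cluster had medians of 0.038 and -0.020, with the sign changing between scalings. The miR-181 family had a median of 0.43 and 0.36 (percentiles 95.2 and 99.3).

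miR-615 was 2.51-fold higher on day 11 in diabetic callus (653 against 261) and miR-208a-5p 3.73-fold higher (253 against 67.8, main 0.95). miR-6332 and miR-128-2-5p were 1.81-fold and 1.66-fold higher, and miR-322-5p 1.31-fold. miR-532-5p was 4.21-fold lower (61.6 against 259.6), with a local background of 77.4% of the spot on day 11. miR-3587, detected on day 11 and not on day 5, was at least 10.4-fold higher blank-corrected and 2.80-fold by the main values, miR-182 at least 2.86-fold and 1.76-fold and miR-433-3p at least 1.94-fold and 1.51-fold. miR-185-3p, detected on day 5 and not on day 11, was at least 3.91-fold lower on day 11 blank-corrected and 1.63-fold by the main values. In all, 6 miRNAs were 2-fold higher and 11 lower among 598 in the main values. Blank-corrected, 17 were higher and 36 lower among 444 detected on both arrays. Under both corrections 4 of these were higher and 10 lower.

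**Figure D3:**
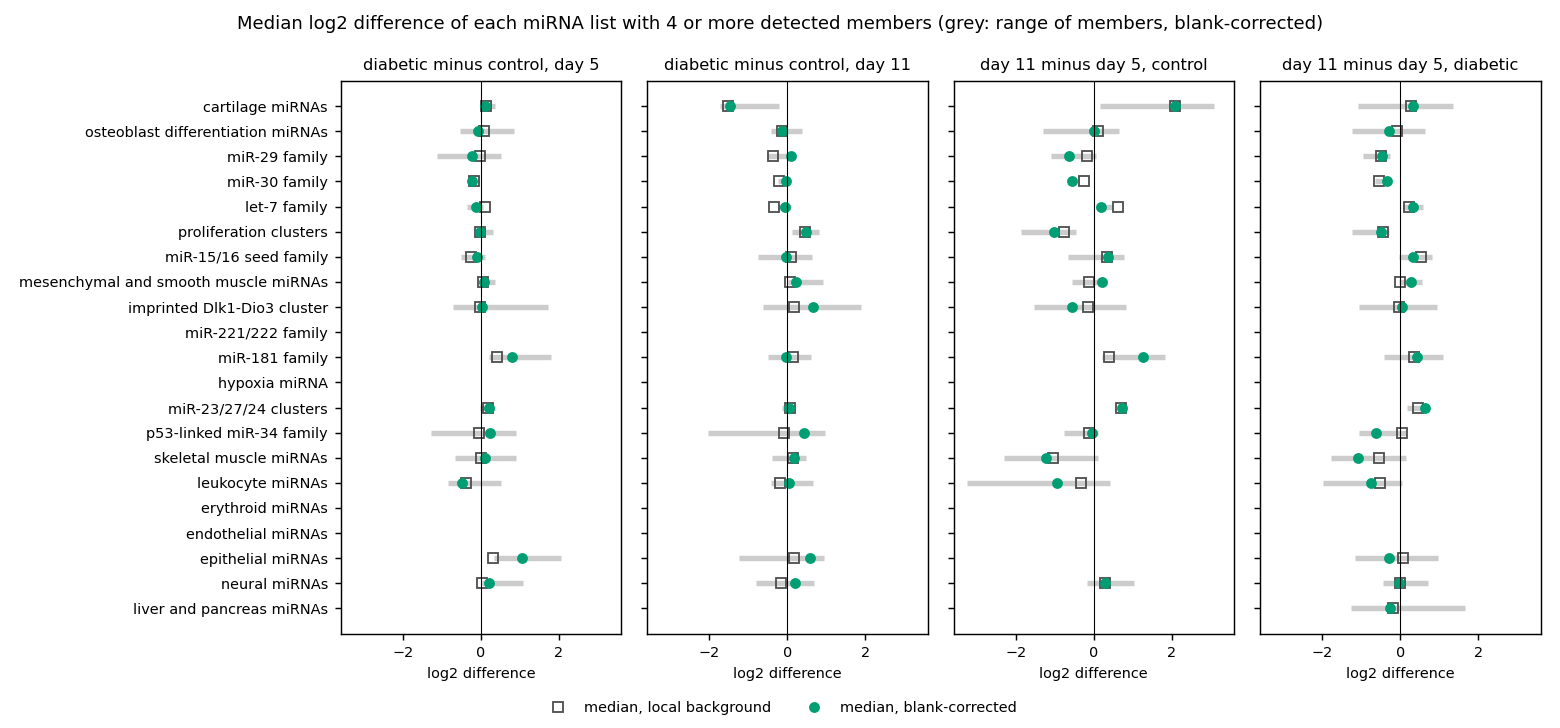
Median log2 difference of each miRNA list in the 4 comparisons with the main values (open squares) and blank-corrected (green circles), with a grey bar for the blank-corrected range of its members and lists of fewer than 4 detected members left blank. The cartilage list lies at -1.46 for diabetic minus control on day 11 and at 2.08 for day 11 minus day 5 in control callus.

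The diabetic differences of the 2 days, which share no array, were weakly related across miRNAs, which are not independent replicates. The correlation was 0.14 (Spearman 0.13) across 507 miRNAs with the main values and 0.18 across 400 blank-corrected. In the main values miR-451-5p was 2-fold higher on both days, where independent lists give 0.024, but its day 11 value was lost with the blank-spot background. Blank-corrected, 2 miRNAs (miR-674-3p and miR-6322) were 2-fold higher and 2 (miR-6216 and miR-6324) 2-fold lower on both days, where independent lists give 0.53 and 0.38. Of these, miR-674-3p, miR-6322 and miR-6324 were named after their values were seen. The time differences of control and diabetic callus, which share no array either, had a correlation of 0.52 (Spearman 0.39) across 518 miRNAs and of 0.54 across 400 blank-corrected. In the main values 4 miRNAs were 2-fold higher and 7 lower on day 11 in both groups, where independent lists give 0.18 and 0.55. Blank-corrected these were 8 and 11, against 1.16 and 2.39.

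The additive limma fit of the main values tested the diabetic difference over both days and the time difference over both groups. The miRNAs with the smallest p for diabetes were miR-6216 (-1.16 ± 0.20 SE, lower on both days), miR-100-5p (-1.18 ± 0.23), miR-3473 (-0.79 ± 0.18), miR-210-3p (-0.72 ± 0.20) and miR-3585-5p among lower ones. Among higher ones they were miR-451-5p, miR-92b-5p, miR-24-3p, miR-494-3p and miR-532-5p. The blank-corrected means were -1.06 for miR-6216, -0.67 for miR-100-5p, -0.43 for miR-3473 and -0.85 for miR-210-3p. For the higher ones, in the order named, they were 0.72, 0.49, 0.13, 0.37 and 0.85. The fitted differences of these were 2.41, 0.67, 0.71, 0.66 and 0.68. None passed, with 0 of 639 miRNAs at a limma adjusted p under 0.05, a smallest adjusted p of 0.815, and 29 at an unadjusted p under 0.05, where 31.95 are expected by chance. For time the smallest limma adjusted p, 0.0848, was shared by miR-1-3p (-1.95 ± 0.18 SE), miR-133a-3p (-1.51 ± 0.17), miR-133b-3p (-1.53 ± 0.18) and miR-142-5p (-1.57 ± 0.18), all lower on day 11 in both groups. miR-223-3p, also lower in both groups, followed with -3.59 ± 0.51 and a limma adjusted p of 0.123. The blank-corrected means of these miRNAs, in the order named, were -1.70, -1.63, -1.62, -1.85 and -2.62. Higher on day 11 in both groups were miR-6332 (1.25 ± 0.17), miR-210-3p (1.30 ± 0.20), miR-128-2-5p (1.17 ± 0.18), miR-615 (0.98 ± 0.17) and miR-326-5p (0.94 ± 0.17), with limma adjusted p between 0.123 and 0.132. Again 0 of 639 passed, and 85 had an unadjusted p under 0.05. The fit has 1 residual degree of freedom and takes the other day or group as its replicate.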

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

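The tests of the local background and of the dimmer array were chosen only after the results were seen, and so was the condition that the value of the dilution test had to exceed the spread of the list medians. The dilution test itself and those on miR-375 were set beforehand. All 6 use the authors' deposited values or detection calls, which rest on the blank spots.

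Among the named miRNAs detected on all 4 arrays, main differences of at least 1.5-fold in opposite directions in the groups compared were found for 3, and none of these differences between groups was tested. By sign alone many more differed, since 50.9% of 507 miRNAs had the same sign of the diabetic difference on both days and 58.5% of 518 the same sign of the time difference in both groups. miR-140-3p had a diabetic minus control difference of 0.70 on day 5 and -1.48 on day 11, with blank-corrected values of 0.15 and -1.73. miR-223-3p had -1.04 on day 5 and 1.05 on day 11, with blank-corrected values of -0.86 and 0.40 and a local background of 80.2% of the spot on the control day 11 array. miR-99a-5p had a day 11 minus day 5 difference of 0.94 in control and -1.06 in diabetic callus, with blank-corrected values of 0.54 and 0.21. Outside the miRNA probes, 12 of 22 single-spot platform probes whose target the files do not name were detected on all 4 arrays. S-Probe1014 had blank-corrected intensities of 27307, 23672, 23296 and 11353 on control day 5, diabetic day 5, control day 11 and diabetic day 11, in the range of the brightest miRNAs.

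The lower cartilage miRNAs of the diabetic callus on day 11 were weighed against 3 other explanations. A local background that follows the spot is argued against by the authors' values, which use none and in which the median difference of miR-140-5p, miR-140-3p, miR-455-5p and miR-455-3p was -1.68. A loss of signal on the dimmer diabetic day 11 array is argued against by the percentile of the cartilage list among random lists of like brightness. It was 0 in those values. The authors' values differ from the blank-corrected ones by a factor per array, so the outcome of both tests was known beforehand. They restate the values given above and are no independent check. Dilution of the cartilage by other cells stays open. It should raise the medians of the muscle, leukocyte, erythroid and endothelial lists alike. In the authors' values 3 of the 4 were at or below 0, which was set beforehand to count against it. However, each lay within its assigned spread of 0. The lowest was -0.0669 with a spread of 0.276, and the highest 0.107 with 0.138. This spread was an SD common to the 4 lists, divided by the square root of the list's number of members. It is not the list's own spread and takes members as replicates. In the authors' values 2 of 2 erythroid, 2 of 3 endothelial, 5 of 9 leukocyte and 3 of 8 muscle members were below 0. The count of 3 of the 4 lists also depends on the scaling. Blank-corrected, the medians were 0.17 for muscle, 0.049 for leukocyte, 0.061 for endothelial and -0.0046 for erythroid miRNAs. A lower content of cartilage, or of these miRNAs in it, in diabetic callus may be the biological counterpart, but 1 pool per group cannot separate diabetes from chance differences between pools.

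The largest day 11 differences of the main values, those of miR-26a-5p, miR-125b-5p, miR-451-5p and miR-26b-5p, were weighed against the local background. All 4 of the 4 had a local background of at least 80% of the spot on the control day 11 array and a difference within 0.5 of 0 in the authors' values, so a background measurement that includes light of the spot may account for them. The outcome of this test too was known beforehand, since the authors' values restate the blank-corrected differences given above. It is no independent check. No biological explanation was tested for this pattern.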

How the results depend on the processing

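Counts are miRNAs that were 2-fold different, with those higher and lower in brackets, in the order diabetic minus control on day 5 and day 11, then day 11 minus day 5 in control and diabetic callus. In the main setting they were 3 (1 and 2), 29 (13 and 16), 46 (19 and 27) and 17 (6 and 11). Normexp on the blank-spot mean was chosen after seeing the data. The cause of a difference between settings was not tested, except that the fold limits and the smaller normexp offset act by their construction. No paired analysis was possible because each group has 1 array and no replicate numbers to pair by, and the additive fit takes day or group as its block. Leaving out 1 pair of arrays leaves the single-day or single-group differences, with no test. Signal over background limits the dim miRNAs, whose differences the offset compresses.

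With a normexp offset of 10 the counts were 20 (10 and 10), 60 (32 and 28), 89 (38 and 51) and 37 (13 and 24). With blank-spot subtraction, median scaling and a floor they were 61 (44 and 17), 57 (26 and 31), 85 (42 and 43) and 82 (25 and 57). With the authors' values they were 98 (91 and 7), 52 (19 and 33), 84 (46 and 38) and 114 (13 and 101). Normexp on the blank-spot mean gave 2 (1 and 1), 9 (2 and 7), 25 (13 and 12) and 16 (6 and 10). At 1.5-fold the counts were 25, 82, 119 and 70, and at 3-fold 0, 9, 15 and 4. Global median scaling gave 4 (3 and 1), 23 (9 and 14), 50 (17 and 33) and 24 (2 and 22), 75th percentile scaling 3 (2 and 1), 23 (9 and 14), 94 (70 and 24) and 41 (31 and 10), and no scaling 4 (1 and 3), 88 (4 and 84), 52 (4 and 48) and 94 (0 and 94). These scalings shifted the median of all miRNAs, by 0.23 and 0.15 (global median) and 0.56 and 0.50 (75th percentile) between the days, and without scaling by -0.11 and -0.68 for diabetic minus control and -0.59 between the days in diabetic callus. In the authors' values the shifts were 0.38, -0.045, 0.10 and -0.35.

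The correlation of the diabetic differences of the 2 days stayed between 0.11 and 0.20 under all alternatives run. The number 2-fold in the same direction on both days, 1 in the main setting, was 2 without scaling, 2 at offset 10, 8 with blank-spot subtraction, 4 in the authors' values, 0 with normexp on the blank-spot mean, 4 at 1.5-fold and 0 at 3-fold. The correlation of the time differences, 0.52, was 0.64 under global median, 75th percentile and no scaling, 0.42 at offset 10 and 0.70 with normexp on the blank-spot mean. The number 2-fold in both groups, 11, was 17 under 75th percentile scaling, 38 without scaling, 18 at offset 10, 24 with blank-spot subtraction, 28 in the authors' values, 44 at 1.5-fold and 2 at 3-fold.

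In the additive limma fit the diabetic count, 0 in the main setting, was 6 (3 and 3) under global median scaling, 6 (3 and 3) under 75th percentile scaling, 7 (3 and 4) without scaling and 2 (0 and 2) with a robust prior. The time count, 0 in the main setting, was 42 (10 and 32) under global median scaling, 249 (226 and 23) under 75th percentile scaling, 51 (2 and 49) without scaling, 3 (0 and 3) with normexp on the blank-spot mean, 5 (0 and 5) with no filter on dim probes, 9 (2 and 7) with a trended prior and 47 (25 and 22) with a robust one.

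The number of lists outside the central 95% of random lists on day 5, 2, was 4 with blank-spot subtraction, 4 in the authors' values and 4 with unmatched random lists. In control callus over time it was 4, and 7, 7 and 7 in those settings and 8 with normexp on the blank-spot mean. In diabetic callus over time it was 4, and 8 with unmatched lists. The cartilage median on day 11 stayed negative under the main setting and 7 alternatives, between -1.65 and -1.17 relative to the median of all miRNAs.

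Called differences changed sign as follows. With blank-spot subtraction, the day 11 differences were -0.081 for miR-26a-5p, -0.34 for miR-125b-5p, -0.036 for miR-451-5p and -0.051 for miR-26b-5p. In the authors' values they were -0.14, -0.40, -0.10 and -0.11, and with normexp on the blank-spot mean -0.16, -0.055 and -0.13 for the last 3. Over time in control callus miR-125b-5p was at 0.45, 0.52 and 0.36 in these 3 settings, miR-451-5p at 1.62, 1.69 and 1.45, and miR-26a-5p at 0.16 and 0.23 in the first 2. Without scaling, the time differences in diabetic callus were -0.084 for miR-6332, -0.054 for miR-140-3p and -0.039 for miR-615, all above the median of all miRNAs in that setting, -0.59, so that these signs follow from the shift of the whole array. Of the other differences of named miRNAs, 61 stayed close to the main value and 3 moved under global median scaling, 63 and 1 under 75th percentile scaling, 28 and 33 without scaling, 57 and 7 at offset 10, 36 and 21 with blank-spot subtraction, 32 and 25 in the authors' values, and 36 and 23 with normexp on the blank-spot mean.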

Other observations

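Both tests on miR-375 in this part were set before their results were seen, and the miRNAs named outside the lists were chosen after their values were seen. Pairs of values give the blank-corrected one first and the main one second.

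The miR-30 family, studied in osteoblast and heart cells, and the miR-29 family, known for targeting collagen transcripts, had negative medians for day 11 minus day 5, all inside the central 95% of random lists in the values given here. The 5 miR-30 miRNAs were all lower in diabetic callus under both corrections, with a median of -0.35 and -0.56 (percentiles 3.88 and 6.51), and 3 of 5 were lower under both corrections in control callus (-0.56 and -0.26, percentiles 6.995 and 16.6). The miR-29 family had 4 of 5 members lower in control callus (-0.64 and -0.18, percentiles 8.66 and 14.5) and 4 of 4 in diabetic callus (-0.48 and -0.50, percentiles 11.4 and 5.12). The let-7 family, which is abundant in differentiated tissue, had 8 of 8 members higher on day 11 in control callus, with a median of 0.19 and 0.62 (percentiles 51.6 and 95.1). In diabetic callus its median was 0.32 and 0.21, and its sign relative to all miRNAs changed under 3 scalings. For diabetic minus control, the let-7 median was -0.14 and 0.10 on day 5 and -0.063 and -0.33 on day 11, with a sign relative to all miRNAs that changed under 3 alternatives on day 5 and under 1 on day 11. The miR-23/27/24 clusters had a median of 0.63 and 0.45 on day 11 against day 5 in diabetic callus, again with a sign that changed under 3 scalings.

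miR-451-5p had levels of 486, 1357, 1495 and 1458 in control day 5, diabetic day 5, control day 11 and diabetic day 11 callus, and miR-144-3p had 26.5, 88.3, 95.6 and 97.45, so that for both the control callus of day 5 was lower than the other 3 pools. Endothelial miR-126a-3p stood at 6414, 5036, 3649 and 3808 in the same order. miR-221-3p stood at 475, 730.4, 367 and 778, with the highest level in diabetic callus on day 11.

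Some further lists are given as medians of diabetic minus control. On day 5 these were -0.072 and 0.081 for osteoblast differentiation miRNAs, 0.066 and 0.060 for mesenchymal and smooth muscle miRNAs, 0.23 and -0.055 for the p53-linked miR-34 family and 0.20 and 0.032 for neural miRNAs. On day 11 they were -0.13 and -0.14 (osteoblast), 0.23 and 0.076 (mesenchymal), 0.43 and -0.079 (miR-34 family), 0.18 and -0.17 (neural) and -0.047 and 0.093 (miR-15/16 seed family). The osteoblast list on day 5, the mesenchymal list on day 5, the miR-34 family on both days, and the neural list and the miR-15/16 seed family on day 11 changed sign between background corrections or scalings.

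miR-375-5p was among the brightest spots of every array, at 20707, 20260.2, 19553 and 24585, although miR-375 is known as a miRNA of pancreatic islets. Of the liver and pancreas miRNAs 0 of 5 were detected on all 4 arrays, which was set beforehand to count against cells of a tissue rich in miR-375. Such cells need not hold the members of that list other than miR-375-3p, so the list cannot decide this. The other arm, miR-375-3p, was detected on 0 arrays. Signal of another RNA on the probe may be the source, but this stays open because no probe sequence was used here and the levels of different probes cannot be set against each other.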
